A study of Caenorhabditis elegans with 18 samples.

How the data were processed

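The data are polyA RNA-seq libraries from whole C. elegans lysates at the L4 stage. The N2 strain and the mutants lin-65(n3441) and met-2(ok2307) were grown from hatch at 20C on bacteria with empty vector or with cco-1 RNAi. Each of the 6 groups has 3 libraries, 18 in all. Per the labels' protocols, RNA was selected with oligo-dT from clarified lysate and libraries were made with the Epicentre ScriptSeq v2 kit. Per the submitters' processing notes, the tools were Bowtie 0.12.7 and DESeq, with no role stated for either. The genome build, annotation, counting tool and strand setting are not given in the sources used here.

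The deposited values are raw read counts per gene model, 1 count column per library. They were checked to be whole numbers of at least 0 with totals that differ between libraries, and the column is used in full (0 columns left unused). Each library lists 20505 gene models under their sequence names, 3365 of them with an isoform letter. Of these, 20071 were matched to a gene of the WBcel235 annotation (Ensembl 115) by sequence name, and the other 434, with 0.159% of all counts, were kept under the sequence name. List members that could not be matched were tin-9.2, hsp-16.1, hsp-16.11, hsp-16.48, hsp-16.49, msd-1, msd-3 and unc-17. Families of near-identical genes, such as major sperm proteins, collagens, vit-3, vit-4 and vit-5, pud genes and heat shock genes, share reads in a way the counts do not show, and overlapping genes on opposite strands may share counts as well.

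Totals ran from 5141303 to 19261705 counts per library, with a median of 14354800. A count of 3 corresponds to 0.153 to 0.510 CPM depending on the library. The 10 most abundant genes took 7.14% to 10.3% of the counts. The first 2 principal components of log2 CPM held 39.5% and 21.9% of the variance. Replicate pairs differed by more than counting noise, with a chi-square per degree of freedom of 11.0 or more.

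Libraries were grouped by title and source. For lin-65 empty vector replicate 1 the strain field reads N2 while title and source read lin-65(n3441), and it was grouped as lin-65. Genes were filtered with filterByExpr by group, which left 15110. The model was fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors and group means for the 18 libraries. All gene tests are edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (robust, two-sided), with a threshold of 0.05, and SE was taken from the log2 fold change and the F value. There were 8 comparisons: cco-1 RNAi against empty vector in each strain, the 3 differences between these responses, and each mutant against N2 on empty vector. Log2 CPM used a prior count of 2.

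The 38 gene lists were tested with camera (limma 3.58.1, two-sided) on log2 CPM with a preset correlation of 0.01, adjusted over the lists within each comparison. The same test with an estimated correlation, and fry, served as alternatives. The lists were: mitochondrial chaperones and proteases, mitochondrial import, regulators of the mitochondrial unfolded protein response, nuclear-encoded respiratory chain, mitochondrially encoded genes, mitochondrial ribosome, cytosolic ribosome, cytosolic heat shock response, endoplasmic reticulum unfolded protein response, glutathione and phase II detoxification, cytochrome P450 enzymes, UDP-glucuronosyltransferases, DAF-16 target genes, innate immune genes, hypoxia response, glycolysis, tricarboxylic acid and glyoxylate cycles, fatty acid metabolism, propionate shunt, heterochromatin and nuclear periphery, synMuv B and DREAM genes, germ granule and meiotic germline genes, oocyte and eggshell genes, sperm genes other than major sperm proteins, major sperm proteins, vitellogenins, furrow and other larval cuticle collagens, adult cuticle collagens, molting genes, all col collagens, body wall muscle, pharynx, intestine, neurons, nuclear hormone receptors, C-type lectins, F-box genes, and glutathione S-transferases. Members were listed from general knowledge of these genes, or by symbol pattern for whole families, and some genes are in more than 1 list.

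Named genes followed a rule. The genes cox-5B (cco-1), lin-65, met-2, hsp-6 and hsp-60 are given in every group. For N2 on cco-1 RNAi and for each mutant against N2, the 10 highest and 10 lowest fold changes were named among genes past the threshold. They also needed fully separated libraries, a mean of at least 5 CPM in the higher group and a symbol of the letters-number form. The 5 highest and 5 lowest were named for lin-65 and met-2 on cco-1 RNAi and for each difference. Up to 4 members with the smallest p were eligible per list and comparison. These comparisons, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined.

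The size of the response was compared between N2 and each mutant on genes called in the other mutant, by an exact two-sided permutation of strain labels within treatment. Overlaps of called genes were set beside the number expected for unrelated lists and, where controls are shared, beside simulated data with no effect. Positions on chromosome arms, outside the middle 1 of 3 equal parts of each of the 5 autosomes, were tested with a two-sided Fisher exact test and by 10000 lists matched on mean expression. The 3′ UTR and coding lengths came from the same annotation and were known for 93.5% of tested genes.

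Alternatives fixed with the comparisons were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no filter, a filter of at least 50 counts in 3 libraries, only the groups compared, the replicate number as a block, a threshold of 0.01, and leaving out each library in turn. When a group keeps 2 libraries its spread is pooled with that of the other groups. Alternatives chosen after seeing the data were 16 libraries (without lin-65 empty vector replicate 1 and met-2 cco-1 RNAi replicate 1), limma voom with library weights, a block in the 6 N2 libraries alone, and removal of each library's trend on 3′ UTR and coding length, alone and combined. Whether equal replicate numbers pair libraries was checked by correlating deviations from the group means. In N2 the numbers matched across treatments (0.13, 0.36 and 0.29), while in lin-65 (0.20, 0.10 and -0.06) and met-2 (-0.28, 0.21 and -0.25) they did not all match. Across strains equal numbers correlated at -0.20 to 0.69.

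The procedure was tested on simulated data with known changes for N2 on cco-1 RNAi (14814 genes). edgeR recovered 24 of 100 genes changed 2-fold and 85 of 100 changed 4-fold, with 5 false calls, so many 2-fold changes go uncalled at this depth and spread. DESeq2 recovered 137 of the 200 with 28 false calls, and weighted voom 112 with 5. Scripts used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.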

Results

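RNA from whole L4 worms was compared between the N2 strain and the mutants lin-65(n3441) and met-2(ok2307) after growth from hatch at 20C on empty vector or on cco-1 RNAi, with 3 libraries in each of 6 groups. The RNAi target cco-1 (now cox-5B) encodes a nuclear subunit of cytochrome c oxidase. Values below are mean ± SD CPM (counts scaled to library size, n = 3 libraries) or log2 fold change ± SE from edgeR. Nothing in the labels says whether replicates are separate cultures, so each p measures the spread between these samples.

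The target itself was lower on cco-1 RNAi in each strain. In N2, cox-5B went from 718 ± 52.1 to 296 ± 14 CPM (log2 fold change -1.28 ± 0.23, adjusted p 0.00827). In lin-65 it went from 586 ± 127 to 278 ± 20.0 CPM (-1.08 ± 0.23, adjusted p 0.0321), and in met-2 from 697 ± 177 to 353 ± 84.9 CPM (-0.98 ± 0.23, adjusted p 0.0407). The 3 differences between these changes were 0.20, 0.30 and 0.10, with adjusted p of 0.999, 0.604 and 0.891. Without N2 cco-1 RNAi replicate 1 or 3, adjusted p in N2 was 0.0623 and 0.0526. In lin-65 it was 0.127 without empty vector replicate 1, and 0.132, 0.143 and 0.112 without cco-1 RNAi replicate 1, 2 or 3. In met-2 it was 0.138, 0.0615 and 0.268 without empty vector replicate 1, 2 or 3, and 0.12 and 0.17 without cco-1 RNAi replicate 2 or 3.

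The strain genes were measured in each group as well. Transcript counts of met-2, a histone H3 lysine 9 methyltransferase gene, were 40.5 ± 2.95 CPM in N2 and 18.8 ± 3.95 in met-2 worms on empty vector (log2 fold change -1.1 ± 0.33, adjusted p 0.0195). That call was lost without N2 empty vector replicate 2 (0.0592), met-2 empty vector replicate 2 (0.0551) or replicate 3 (0.0649). On cco-1 RNAi met-2 had 48.8 ± 8.50 CPM in N2 and 15.9 ± 8.67 in met-2 worms, and in lin-65 worms it had 38.5 ± 3.79 and 46.3 ± 7.24 CPM on the 2 diets. The lin-65 gene, whose product acts with MET-2, had 13.4 ± 1.23 CPM in N2 and 6.88 ± 1.49 in lin-65 worms on empty vector (-0.96 ± 0.37, adjusted p 0.329). With the 2 libraries farthest from their mates left out (16 libraries, chosen after seeing the data), that adjusted p was 0.0442, and its range over 10 alternatives was 0.00199 to 0.368. On cco-1 RNAi lin-65 had 26.1 ± 3.80 CPM in N2 (0.96 ± 0.36, adjusted p 0.208) and 9.60 ± 1.63 in lin-65 worms. In met-2 worms lin-65 had 23.6 ± 3.05 CPM on empty vector and 20.9 ± 12.7 on cco-1 RNAi.

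The mitochondrial chaperone gene hsp-6 is a common reporter of mitochondrial stress. It had 285 ± 61.5 CPM in N2 on empty vector and 612 ± 60.7 on cco-1 RNAi, every RNAi library above every control library, but did not pass the test (log2 fold change 1.1 ± 0.42, adjusted p 0.208). Over 12 alternatives this adjusted p ranged from 5.85e-04 to 0.230, and 5 of them put hsp-6 past 0.05. In lin-65 it had 310 ± 133 and 514 ± 39.2 CPM (0.73 ± 0.42, adjusted p 0.476), again with every RNAi library above every control library. The lowest control there, empty vector replicate 1 (165 CPM), is among the libraries farthest from their mates. In met-2 hsp-6 had 623 ± 143 CPM on empty vector and 767 ± 503 on cco-1 RNAi (0.30 ± 0.41, adjusted p 0.853). There RNAi replicate 1, also among the libraries farthest from their mates, lay at 248 CPM, and replicates 2 and 3 at 803 and 1251 CPM. The differences from N2 were -0.37 ± 0.59 for lin-65 (adjusted p 0.999) and -0.80 ± 0.59 for met-2 (adjusted p 0.446). Each includes a library that lies far from its mates, so neither shows a weaker response in the mutant. Between the strains on empty vector, hsp-6 in met-2 exceeded N2 by 1.13 ± 0.42 (adjusted p 0.0502). That value passed under 9 of 10 alternatives (range 1.10e-04 to 0.0501), and was 0.0455 without met-2 empty vector replicate 3. The partner chaperonin gene hsp-60 had 510.4 ± 42 and 417 ± 33 CPM in N2 (-0.29 ± 0.20, adjusted p 0.443). Its levels were 536 ± 155 and 529 ± 44.7 CPM in lin-65, and 524 ± 32.7 and 699 ± 99.8 CPM in met-2 (0.42 ± 0.20, adjusted p 0.536).

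**Figure D1:**
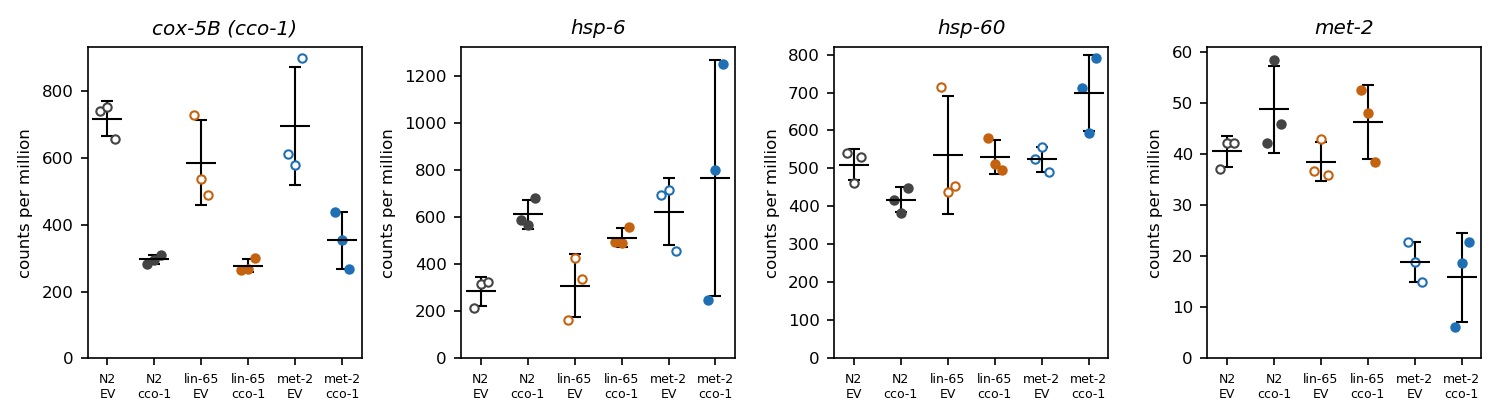
CPM per library of cox-5B, hsp-6, hsp-60 and met-2 in the 6 groups, with mean ± SD (n = 3); open points are empty vector and filled points cco-1 RNAi. The target cox-5B is lower on RNAi in each strain (718 to 296 CPM in N2), and met-2 is low in the met-2 strain (18.8 CPM on empty vector).

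On cco-1 RNAi in N2, the highest fold changes included acs-2, hrg-2 and several cytochrome P450 genes, and the lowest included pud genes, fat-7 and yolk genes. The acyl-CoA synthetase gene acs-2 rose from 2.44 ± 1.14 to 47.6 ± 7.96 CPM (log2 fold change 4.35 ± 0.44, adjusted p 5.28e-05), and the heme-responsive gene hrg-2 from 4.13 ± 1.29 to 63.7 ± 12.5 CPM (3.92 ± 0.31, 3.67e-06). Cytochrome P450 genes were prominent: cyp-33C8 (3.72 ± 0.33), cyp-13A12 (3.09 ± 0.40) and cyp-14A4, which had 0.195 CPM on empty vector and 7.39 on cco-1 RNAi. The glucuronosyltransferase genes ugt-62 (61.7 ± 16 to 409 ± 56.5 CPM) and ugt-19 (2.57 ± 0.27) rose too, as did the lectin gene clec-47 (3.13 ± 0.47), the neuropeptide-like gene nlp-8 (3.12 ± 0.61) and srlf-34 (2.65 ± 0.31). Of the genes that fell, pud-4 and pud-1.2, of a family named for proteins raised in daf-2 mutants, had the lowest values (-4.05 ± 0.53 and -3.89 ± 0.50), beside pud-3 (-3.26 ± 0.42). The stearoyl-CoA desaturase gene fat-7 fell from 11 ± 5.94 to 1.72 ± 0.382 CPM (-2.72 ± 0.37, adjusted p 6.36e-04), and the lectin gene clec-86 fell by 2.04 ± 0.27 on the log2 scale. The yolk genes vit-3 (-2.67 ± 0.50, adjusted p 0.0130) and vit-4 (-2.32 ± 0.47), the sphingomyelinase gene asm-3 (-2.31 ± 0.50), cdd-1 (-2.01 ± 0.39) and the lysozyme gene lys-7 (-1.83 ± 0.35) fell as well.

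Several of these N2 calls were lost when 1 library was left out, most of them without any of several different libraries. Without N2 empty vector replicate 2, adjusted p was 0.0759 for vit-3, 0.143 for vit-4, 0.162 for asm-3, 0.0796 for cdd-1 and 0.0966 for nlp-8. Empty vector replicate 1 mattered for nlp-8 (0.0846), cdd-1 (0.0639) and lys-7 (0.0947), and replicate 3 for vit-4 (0.0544) and asm-3 (0.106). Leaving out cco-1 RNAi replicate 1 gave 0.0986 for vit-3, 0.142 for vit-4, 0.194 for asm-3, 0.115 for cdd-1, 0.0567 for lys-7 and 0.0531 for nlp-8. Leaving out replicate 3 gave 0.104, 0.164, 0.198, 0.0950, 0.119 and 0.0666 for the same genes, and leaving out replicate 2 gave 0.0654 for cdd-1 and 0.0590 for lys-7. The remaining 14 of the 20 genes kept an adjusted p under 0.05 without any 1 N2 library.

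In all, 82 genes were higher and 45 lower on cco-1 RNAi in N2 (127 of 15110 tested), and 200 (114 higher, 86 lower) with the replicate number as a block. The count was 64, 55 and 71 without N2 empty vector replicate 1, 2 or 3, and 58, 74 and 50 without cco-1 RNAi replicate 1, 2 or 3. Through the shared spread, libraries of other strains moved it too, to 863 without met-2 cco-1 RNAi replicate 1 and 234 without lin-65 empty vector replicate 1. With 16 libraries it was 2828 (1770 higher, 1058 lower). A replicate block in the 6 N2 libraries alone, chosen after seeing the data, gave 4351.

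Among the 38 gene lists, camera (limma) gave 8 an adjusted p under 0.05 in N2. Cytochrome P450 genes (54, 8 rose and 0 fell; 11 and 3 adjusted over the list alone) went up with a median of 0.31 (adjusted p 0.00103), led by cyp-13A8 (3.67 ± 0.39). The 6 vitellogenins, yolk protein genes, went down (median -1.37, 2 fell, 3 over the list alone, adjusted p 0.00103). Cytosolic ribosomal protein genes (79, median -0.47, adjusted p 8.66e-07), mitochondrial ribosomal protein genes (69, median -0.34, 0.00103) and major sperm protein genes (29, median -0.68, 8.86e-04) went down with 0 members past the threshold over all genes by edgeR. Glutathione S-transferases (41, median -0.48, 1 fell, over the list alone 1 rose and 6 fell) had 0.00103, led by gst-10 (-1.79 ± 0.30; 0.0526 without cco-1 RNAi replicate 3). The nuclear-encoded respiratory chain (35, median -0.22, 0.0149; 0.0527 without empty vector replicate 2 and 0.0724 without cco-1 RNAi replicate 2) also went down. Endoplasmic reticulum unfolded protein response genes (17, median 0.32) had 0.0344 (0.107 and 0.119 without empty vector replicate 1 or 2, 0.0861 without cco-1 RNAi replicate 3). Each of the 8 lists had an adjusted p of 0.766 with an estimated correlation.

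The 11 mitochondrial chaperone and protease genes were not shifted in N2 (median 0.04, adjusted p 0.942), nor were the 14 mitochondrial import genes (median -0.14, 0.883). The import receptor gene tomm-70 had 0.78 ± 0.18 (adjusted p 0.0414), and 0.0644 to 0.210 when any 1 of the 6 N2 libraries was left out. UDP-glucuronosyltransferases (63, 8 rose and 1 fell; 12 and 3 over the list alone) had 0.0546, and fatty acid metabolism (28, median -0.28, 1 rose and 1 fell) had 0.195. Lists that passed in none of the 8 comparisons had these values in N2: regulators of the mitochondrial unfolded protein response, median 0.38 and adjusted p 0.228; hypoxia response, -0.26 and 0.368; synMuv B and DREAM genes, 0.14 and 0.665. Glutathione and phase II detoxification genes had a median of -0.43 and adjusted p 0.368. For cytosolic heat shock genes the median was 0.11 and the mean -0.04 (0.965), and for heterochromatin and nuclear periphery genes 0.12 and -0.02 (0.754). DAF-16 target genes (17, 2 rose and 1 fell; 3 and 5 over the list alone) had a mean of -0.20 and adjusted p 0.441.

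**Figure D2:**
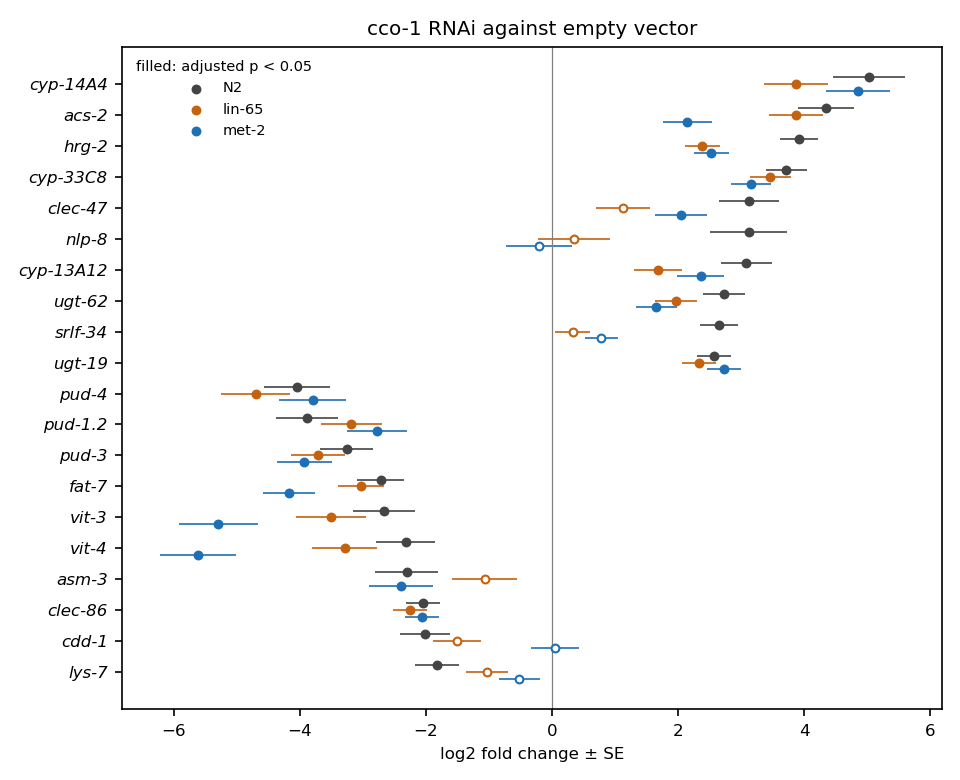
Log2 fold change ± SE on cco-1 RNAi in N2, lin-65 and met-2 of the 20 genes named for N2 (n = 3 libraries per group); filled points have adjusted p under 0.05. Genes such as acs-2 (4.35, 3.88 and 2.14) and pud-4 (-4.05 in N2 and -4.70 in lin-65) moved the same way in the 3 strains. Not all did: in met-2 the mean went from 8.71 to 7.65 CPM for nlp-8 and from 37.1 to 38.3 CPM for cdd-1.

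In lin-65 worms many of the same genes moved on cco-1 RNAi. The highest were acs-2 (2.44 ± 1.59 to 36.5 ± 6.18 CPM, log2 fold change 3.88 ± 0.43, adjusted p 2.33e-04), cyp-14A4 (3.87 ± 0.50), cyp-33C8 (3.46 ± 0.33), hrg-2 (2.38 ± 0.28) and ugt-19 (2.33 ± 0.27). The lowest were pud-4 (-4.70 ± 0.55), pud-3 (-3.72 ± 0.43) and the yolk genes vit-3 (-3.51 ± 0.55), vit-4 (-3.29 ± 0.51) and vit-1 (-3.21 ± 0.69). The desaturase gene fat-7 fell from 24.5 ± 4.14 to 2.96 ± 0.213 CPM (-3.03 ± 0.36, adjusted p 2.34e-04). Without cco-1 RNAi replicate 3, vit-3 had 0.0501. For vit-1 (0.0359) adjusted p was 0.0813 and 0.0866 without empty vector replicate 2 or 3, and 0.154, 0.0604 and 0.231 without cco-1 RNAi replicate 1, 2 or 3. In all 41 genes were higher and 67 lower (108), against 173 (58 and 115) with 16 libraries. The count was 65 without lin-65 empty vector replicate 3 and 51, 63 and 33 without cco-1 RNAi replicate 1, 2 or 3. Without met-2 cco-1 RNAi replicate 1, which only shares the spread, it was 226.

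Cuticle and yolk genes made up the strongest list shifts in lin-65. The 128 col collagens had a median of -0.70 (1 fell; over the list alone 1 rose and 31 fell; adjusted p 3.70e-17), led by col-135 (-3.64 ± 0.64, adjusted p 0.00867; 0.0618 without cco-1 RNAi replicate 2). Vitellogenins had a median of -2.88 (5 of 6 fell, 6 over the list alone, 3.62e-11). C-type lectins (129, median -0.33, 1 rose and 2 fell; 1 and 7 over the list alone) had 0.00393, with clec-86 at -2.25 ± 0.27. Cytosolic ribosomal protein genes had a median of -0.34 (6.15e-04; 0.328 without lin-65 empty vector replicate 1, 0.242 with 16 libraries). Glutathione S-transferases (median -0.21, 4 fell over the list alone) had 0.0190, and 0.303 without empty vector replicate 1. The tricarboxylic acid and glyoxylate cycles (22, median 0.17) had 0.0190, and 0.0627 without cco-1 RNAi replicate 1. Adult cuticle collagens (7, median -0.73, 2 fell over the list alone) had 0.0326 (0.0980 and 0.0559 without empty vector replicate 2 or 3, 0.104 without cco-1 RNAi replicate 1). Germ granule and meiotic genes (29, median 0.29) had 0.0330 (0.116 without empty vector replicate 1, 0.0871 without cco-1 RNAi replicate 1). Adjusted p with an estimated correlation was 0.295 for vitellogenins, 0.538 for col collagens, 0.773 for adult cuticle collagens and 0.791 for the others. With the 3′ UTR trend described below removed, C-type lectins had a median of -0.13 (adjusted p 0.146), cytosolic ribosomal protein genes 0.06 (0.659), glutathione S-transferases 0.05 (0.411), the tricarboxylic acid cycle 0.10 (0.628), adult cuticle collagens -0.52 (0.118) and germ granule genes 0.17 (0.362). Removed in 16 libraries, C-type lectins (-0.12, 0.0141) and adult cuticle collagens (-0.81, 0.0302) passed and the other 4 did not. The mitochondrial chaperone list had a median of 0.20 and adjusted p 0.250.

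In met-2 worms the yolk genes had the lowest fold changes on cco-1 RNAi. The vitellogenin gene vit-2 fell from 578 ± 245 to 22.9 ± 3.07 CPM (log2 fold change -4.65 ± 0.54, adjusted p 1.16e-04), and vit-4 (-5.62 ± 0.60), vit-1 (-5.58 ± 0.78) and vit-3 (-5.30 ± 0.62) fell further. The desaturase gene fat-7 fell from 13.4 ± 4.74 to 0.727 ± 0.0877 CPM (-4.17 ± 0.41). Detoxification genes rose: cyp-14A4 (0.503 ± 0.0792 to 15 ± 2.39 CPM, 4.85 ± 0.51), cyp-13A8 (3.58 ± 0.35), cyp-33C8 (27 ± 2.15 to 241 ± 14 CPM, 3.16 ± 0.32) and ugt-19 (2.72 ± 0.27). The ammonium transporter gene amt-1 rose by 2.84 ± 0.50 (adjusted p 0.00523; 0.0557 without empty vector replicate 1) and acs-2 by 2.14 ± 0.39 (0.00622; 0.0702 without empty vector replicate 2). Among the lowest was also pud-1.1 (-5.12 ± 0.98, adjusted p 0.01; 0.0768 without cco-1 RNAi replicate 2). In all 82 genes were higher and 85 lower (167), against 300 (116 and 184) with 16 libraries. The count was 93 and 91 without met-2 empty vector replicate 1 or 2, and 109 without cco-1 RNAi replicate 2.

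Camera gave 20 lists an adjusted p under 0.05 in met-2, 7 of which kept it without any 1 met-2 library. These were vitellogenins (median -4.98, 6 of 6 fell, 4.96e-22), UDP-glucuronosyltransferases (0.46, 7 rose; 9 rose and 1 fell over the list alone; 1.11e-05) and mitochondrial import (0.54, 2 rose over the list alone, 3.13e-05). The others were adult cuticle collagens (-1.45, 1 fell, 4 over the list alone, 8.21e-05), cytochrome P450 genes (0.32, 6 rose; 11 rose and 2 fell over the list alone; 1.48e-04), glycolysis (19 genes, 0.46, 9.43e-04) and mitochondrial chaperones and proteases (0.42, 1 rose over the list alone, 9.43e-04). Members behind these shifts were tomm-70 (0.66 ± 0.17, adjusted p 0.0926), tomm-20 (0.66 ± 0.18, 0.0972), the prohibitin gene phb-2 (0.64 ± 0.17, 0.0938) and the adult collagen gene col-7 (-2.93 ± 0.61, 0.0195). For col-7 it was 0.0694 and 0.126 without empty vector replicate 1 or 2, and 0.0801 and 0.0961 without cco-1 RNAi replicate 2 or 3. With an estimated correlation, in the same order, adjusted p was 0.0256, 0.255, 0.0856, 0.0904, 0.230, 0.0841 and 0.151.

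Each of the other 13 lists in met-2 lost its call without at least 1 met-2 library. They had adjusted p of 0.151 to 0.654 with an estimated correlation. Cco-1 RNAi replicate 1 bore on the mitochondrial ribosome (median 0.30, 0.00176; 0.918 without it), glutathione S-transferases (0.20, 0.0248; 0.918), innate immune genes (25, 0.31, 0.0360; 0.854) and endoplasmic reticulum unfolded protein response genes (-0.34, 0.0123; 0.503). It bore as well on F-box genes (134, 0.16, 0.0297; 0.373), molting genes (23, -0.24, 0.0107; 0.349), the respiratory chain (0.12, 0.0189; 0.175) and oocyte and eggshell genes (20, -0.39, 9.43e-04; 0.101). Without cco-1 RNAi replicate 3, major sperm proteins (-0.15, 0.00921) had 0.759, col collagens (-0.10, 0.0134) 0.379, nuclear hormone receptors (187, 0.13, 0.0163) 0.193, the propionate shunt (7, -0.19, 0.0360) 0.125 and oocyte genes 0.0670. Without replicate 2, col collagens had 0.385, F-box genes 0.261, the propionate shunt 0.160, nuclear hormone receptors 0.0612 and fatty acid metabolism (28, -0.24, 0.0110) 0.0560. Of the empty vector libraries, replicate 1 bore on innate immune genes (0.179), the respiratory chain (0.179) and glutathione S-transferases (0.148). Replicate 2 bore on nuclear hormone receptors (0.144), glutathione S-transferases (0.114) and major sperm proteins (0.0793), and replicate 3 on col collagens (0.269), F-box genes (0.181) and the propionate shunt (0.181). With 16 libraries the mitochondrial ribosome, innate immune genes and glutathione S-transferases had an adjusted p of 0.939 each, in the opposite direction. Removing the 3′ UTR trend gave a median of -0.16 for endoplasmic reticulum unfolded protein response genes (0.255), 0.15 for innate immune genes (0.307), 0.11 for F-box genes (0.307), -0.13 for the propionate shunt (0.0614) and 0.03 for glutathione S-transferases (0.364). Molting genes had 0.0504 with a median of about the same size (-0.20). Removed in 16 libraries, the propionate shunt passed (-0.35, 0.00167) and the mitochondrial ribosome had 0.208 (median 0.11). The respiratory chain had 0.106 there with its median unchanged at 0.12, so that loss is not one of fold.

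**Figure D3:**
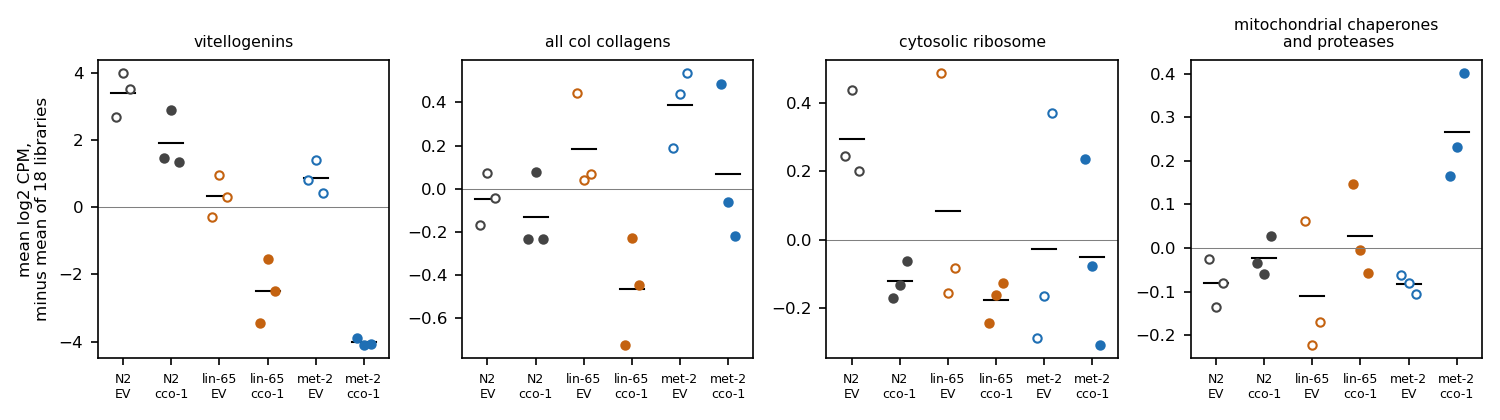
Mean log2 CPM of 4 gene lists in each library, as the difference from the mean of the 18 libraries; bars are group means (n = 3), open points empty vector and filled points cco-1 RNAi. Vitellogenins go down on RNAi in each strain, with median log2 fold changes of -1.37 in N2, -2.88 in lin-65 and -4.98 in met-2.

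Many called genes were shared between strains. Of the genes called in N2 and in lin-65, 31 were higher and 19 lower in both responses, where 0.223 and 0.2 would be expected for unrelated lists. N2 and met-2 shared 36 higher and 15 lower genes (0.445 and 0.253 expected), and lin-65 and met-2 33 and 41 (0.223 and 0.377), with 0 genes in opposite directions in each pair. These responses share no library. With 16 libraries the shared counts were 112, 143 and 109, with 2 genes in opposite directions for N2 and met-2. Across all tested genes, which are not independent replicates, the correlation of log2 fold changes was 0.61 for N2 and lin-65, -0.06 for N2 and met-2 and 0.07 for lin-65 and met-2. With 16 libraries the 3 correlations were 0.36, 0.27 and 0.37.

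Response size was compared on genes chosen in a strain outside the pair. For the 167 genes called in met-2, the mean response aligned by direction was 1.05 in N2 and 1.49 in lin-65 (two-sided exact permutation p 0.270, 400 assignments). Those higher in met-2 had a median log2 fold change of 1.12 in N2 and 0.96 in lin-65, and those lower fell by a median of 0.70 and 1.42. For the 108 genes called in lin-65, the mean response was 1.52 in N2 and 2.04 in met-2 (two-sided exact permutation p 0.510). The medians were 1.83 and 1.76 for the higher genes and falls of 1.01 and 1.62 for the lower ones. The mutant minus N2 differences were 0.44 (SE 0.21) for lin-65 and 0.52 (SE 0.22) for met-2. By fitted fold changes the response was smaller than in N2 for 61 of the 167 genes in lin-65 and 53 of the 108 in met-2. The smallest p these assignments can give is 0.0025. Strain labels were permuted separately within each treatment, so strain differences on empty vector widen the reference values. In simulated data with a true difference of -1 the exact permutation p was 0.055. These p values therefore cannot show that the responses are of equal size.

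Differences between strains in the cco-1 RNAi response depended on how the libraries were modelled. The planned edgeR fit of the 18 libraries called no gene. For lin-65 minus N2, 0 genes passed (480 at an unadjusted p under 0.05, smallest adjusted p 0.130; DESeq2 5). For met-2 minus N2, 0 genes passed (2603 unadjusted, smallest adjusted p 0.0620; DESeq2 153), and for met-2 minus lin-65 0 (1723 unadjusted, 0.432; DESeq2 1). Splits that mix the treatments within each strain separately gave up to 3834, 3214 and 3175 genes at an unadjusted p under 0.05. For met-2 minus N2 the split after the highest gave 1210. Such a split can carry the cco-1 RNAi response itself into the difference, so its count is no reference for equal responses. The unadjusted counts alone therefore neither show nor exclude a difference. With the replicate number as a block edgeR called 0, 32 (3 higher, 29 lower) and 0 genes, and without a filter on low counts 0, 12 and 0. The weighted limma voom fit called 50, 2382 and 126 genes, and 16 libraries gave 23, 127 and 1. With the 3′ UTR trend removed edgeR called 3, 42 and 1, the same in 16 libraries 33, 134 and 1, and only the groups compared 0, 4 and 0. Leaving out met-2 cco-1 RNAi replicate 1 gave 11 genes for met-2 minus N2 and 1 for lin-65 minus N2. For met-2 minus N2, leaving out N2 empty vector replicate 3 gave 1, lin-65 empty vector replicate 1 gave 21, and lin-65 cco-1 RNAi replicate 1 or 2 gave 8 and 3. Leaving out lin-65 cco-1 RNAi replicate 1 gave 1 for met-2 minus lin-65. Yolk genes came closest: the response in met-2 minus that in N2 was -3.91 ± 0.68 for vit-2 and -4.41 ± 0.77 for vit-6 (adjusted p 0.0620 each). In N2 vit-6 had 2151 ± 746 CPM on empty vector and 2118 ± 1164 on cco-1 RNAi, and in met-2 897 ± 370 and 41.5 ± 5.4 CPM. The vitellogenin list differed between met-2 and N2 (median -3.73, adjusted p 2.10e-07, 6 of 6 lower over the list alone) and between lin-65 and N2 (-1.50, 4.90e-04). The 2 values with an estimated correlation were 0.493 and 0.555.

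On empty vector, genes that differed between lin-65 and N2 included cnc-4, scrm-4, col-73 and vit-3. The antimicrobial peptide gene cnc-4 was higher in lin-65 (15.3 ± 2.52 to 123 ± 35.4 CPM, log2 fold change 3.01 ± 0.40, adjusted p 3.85e-04). Among the highest were also the scramblase gene scrm-4 (4.04 ± 0.510 to 35.6 ± 10.3 CPM, 3.12 ± 0.24, 5.96e-07), the calcium sensor gene ncs-6 (2.96 ± 0.594 to 41 ± 5.69 CPM, 3.81 ± 0.25), pals-14 (3.4 ± 0.50), pals-6 (2.94 ± 0.57) and the fatty acid binding gene far-3 (3.22 ± 0.43). The others were mihp-1 (3.34 ± 0.34), nspe-4 (2.99 ± 0.42), the RNA-directed RNA polymerase gene rrf-2 (2.22 ± 0.36) and the chemoreceptor gene sri-62, at 0.0946 CPM in N2 and 5.71 ± 1.52 in lin-65. The collagen gene col-73 was lower (1429 ± 329 to 214 ± 9.73 CPM, -2.74 ± 0.23, 1.43e-06), as were vit-3 (435 ± 189 to 24.4 ± 6.15 CPM, -4.16 ± 0.53), vit-4 (-3.43 ± 0.49), vit-5 (-3.29 ± 0.51), cin-4 (-3.76 ± 0.53) and exh-1 (-2.27 ± 0.29). Lower too were vit-2 (-2.44 ± 0.48), vit-6 (-2.33 ± 0.54), asm-3 (-2.11 ± 0.50) and the potassium channel subunit gene mps-2 (-1.85 ± 0.44), with adjusted p of 0.0129 to 0.0445.

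These last 4 genes and pals-6 lost their calls without any 1 of several different libraries. Without N2 empty vector replicate 2, adjusted p was 0.0702 for vit-2, 0.177 for vit-6, 0.188 for asm-3, 0.157 for mps-2 and 0.0608 for pals-6. Without replicate 3 it was 0.121 for vit-6, 0.148 for asm-3, 0.159 for mps-2 and 0.0836 for pals-6, and without replicate 1 it was 0.0776 for mps-2 and 0.0526 for pals-6. Leaving out lin-65 empty vector replicate 1 gave 0.0532 for vit-2, 0.0923 for vit-6, 0.0753 for asm-3 and 0.0516 for mps-2. Replicate 3 gave 0.0708, 0.149, 0.144 and 0.147 for the same 4, and replicate 2 gave 0.115 for asm-3. In all 161 genes were higher and 53 lower in lin-65 (214), against 523 (357 and 166) with 16 libraries. The count was 134, 99 and 107 without N2 empty vector replicate 1, 2 or 3, and 136 without lin-65 empty vector replicate 3. Without met-2 cco-1 RNAi replicate 1, which only shares the spread, it was 342.

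By list, vitellogenins (median -2.92, 5 of 6 fell, 6 over the list alone, adjusted p 8.00e-15) and the nuclear-encoded respiratory chain (-0.32, 4 fell over the list alone, 2.04e-09) were lower in lin-65. The respiratory gene with the smallest p was ucr-11 (-1.05 ± 0.27, adjusted p 0.0671). The tricarboxylic acid cycle (-0.25, 2.88e-04) and the propionate shunt (-0.49, 0.00150; 0.0769 without lin-65 empty vector replicate 1) were lower as well. C-type lectins (0.33, 7 rose; 18 rose and 5 fell over the list alone; 3.95e-04), innate immune genes (0.34, 1 rose, 4 over the list alone, 5.40e-04) and col collagens (0.34, 11 rose and 1 fell; 22 and 5 over the list alone; 5.63e-04) were higher. Leading lectin members were clec-126 (4.07 ± 0.58) and clec-64 (1.64 ± 0.29). F-box genes (0.19, 5 rose and 1 fell; 9 and 1 over the list alone) had 0.0216, with fbxa-158 at 4.34 ± 0.77 (adjusted p 0.00592; 0.0573 without N2 empty vector replicate 3). Without lin-65 empty vector replicate 1, col collagens had 0.0769 and F-box genes 0.0882. Cytosolic (-0.11, 3.35e-04; 0.185 without lin-65 empty vector replicate 2) and mitochondrial ribosomal protein genes (-0.11, 0.0140; 0.442 and 0.104 without replicate 2 or 3) were slightly lower. Body wall muscle genes (19, -0.17, 0.0140) had 0.0838 without N2 empty vector replicate 1 and 0.0718 without lin-65 empty vector replicate 1. Glycolysis (-0.17, 0.0411) had 0.141 and 0.0916 without N2 replicate 1 or 2, and 0.165 and 0.170 without lin-65 replicate 2 or 3. With the 3′ UTR trend removed, F-box genes had a median of 0.11 and 0.298 (0.157 in 16 libraries), and glycolysis 0.0803 at an unchanged median of -0.17 (0.00150 in 16 libraries). These 12 lists had, with an estimated correlation, adjusted p of 0.0993 (vitellogenins and respiratory chain) to 0.890.

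The met-2 strain differed from N2 far more widely on empty vector. The polo-like kinase gene plk-3 was almost absent (165 ± 38.9 to 0.415 ± 0.317 CPM, log2 fold change -8.54 ± 0.48, adjusted p 3.86e-09). The thioredoxin gene trx-2 (108 ± 13 to 5.94 ± 1.48 CPM, -4.19 ± 0.37), the carrier gene slc-25A18.2 (-4.01 ± 0.33) and the spastin gene spas-1 (69.4 ± 16 to 8.73 ± 0.628 CPM, -2.99 ± 0.23) were lower, with cin-4 (-3.78 ± 0.52) and plg-1 (-3.21 ± 0.55). The heat shock genes hsp-70 (-3.64 ± 0.44) and hsp-16.41 (-3.21 ± 0.71) were lower, and so were vit-3 (-3.90 ± 0.52) and vit-4 (-3.27 ± 0.49). The genes named as higher included collagen genes: col-41 (21.2 ± 5.73 to 708 ± 124 CPM, 5.06 ± 0.51, 1.40e-05), col-166 (63.3 ± 13.3 to 895 ± 257 CPM, 3.82 ± 0.34), col-176 (3.81 ± 0.54), col-54 (3.75 ± 0.39) and col-3 (3.49 ± 0.66). The cuticle gene dpy-1 (3.47 ± 0.50), scrm-4 (4.04 ± 0.510 to 112 ± 3.77 CPM, 4.78 ± 0.25), srlf-34 (4.63 ± 0.32), the FK506-binding gene fkb-8 (3.68 ± 0.31) and trf-2 (0.127 to 6.73 CPM) were also higher. In all 2306 genes were higher and 2310 lower (4616), and 7517 (3884 and 3633) with 16 libraries. The count was 2411 without N2 empty vector replicate 2, and 2800 and 2864 without met-2 empty vector replicate 1 or 3.

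**Figure D4:**
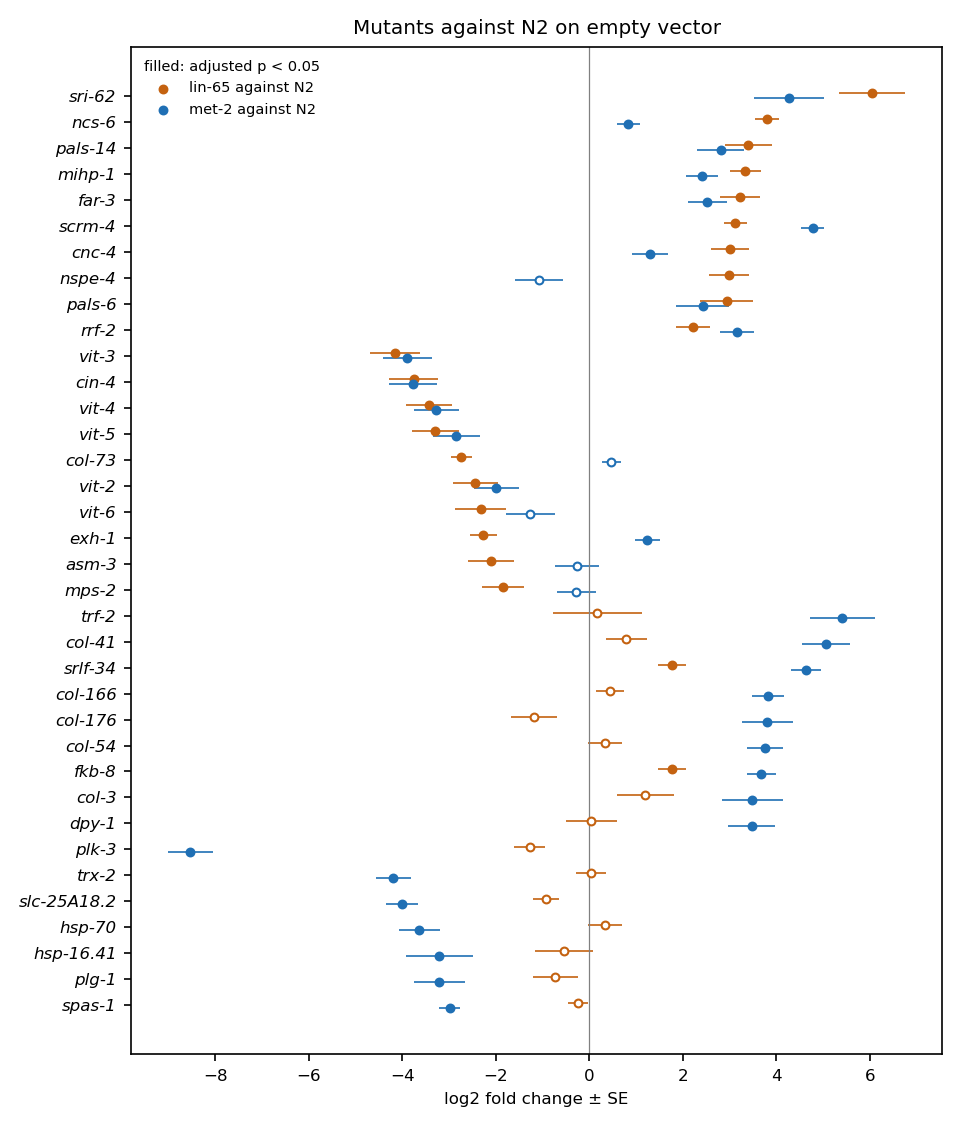
Log2 fold change ± SE against N2 on empty vector in lin-65 and met-2 (n = 3 libraries per group) of the 36 genes named for these 2 comparisons; filled points have adjusted p under 0.05. The gene plk-3 lies lowest in met-2 (-8.54), and scrm-4 and the vitellogenin genes move the same way in both mutants.

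By list, camera with the preset correlation called changes in several directions. Lower in met-2 were gamete and yolk genes: major sperm proteins (median -1.47, 16 of 29 fell, 20 over the list alone, adjusted p 2.21e-07), oocyte and eggshell genes (-1.16, 11 of 20, 15 over the list alone, 7.09e-06), sperm genes other than major sperm proteins (-1.04, 14 of 25 fell; 1 rose and 15 fell over the list alone; 0.00141), germ granule and meiotic genes (-0.56, 11 of 29, 12 over the list alone, 0.00210) and vitellogenins (-2.43, 5 of 6, 6 over the list alone, 2.60e-04). Single members were msp-10 (-1.87 ± 0.37), the eggshell gene cbd-1 (-1.65 ± 0.29), msd-2 (-2.04 ± 0.33) and the germline helicase gene glh-2 (-1.32 ± 0.23). Higher were innate immune genes (1.22, 14 rose and 1 fell; 18 and 1 over the list alone; 3.02e-06), endoplasmic reticulum unfolded protein response genes (1.06, 13 of 17 rose, 4.57e-06) and C-type lectins (0.85, 56 rose and 13 fell; 59 and 15 over the list alone; 7.09e-06). They included irg-5 (2.73 ± 0.38), clec-4 (2.36 ± 0.28), the chaperone gene dnj-7 (1.59 ± 0.26) and the calreticulin gene crt-1 (1.11 ± 0.20). None of these 8 lists passed with an estimated correlation (adjusted p 0.377 to 0.468).

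Some lists of somatic tissues were higher in met-2 too, while body wall muscle (median 0.21, 5 rose and 1 fell) did not pass (adjusted p 0.357). The counts are relative and come from whole worms. Shifts of these and of the gamete lists therefore cannot be told from changes in tissue share or developmental timing, which were not measured. Neuron genes (median 1.19, 14 of 22 rose, 15 over the list alone, adjusted p 2.70e-05) included the proprotein convertase gene egl-3 (1.91 ± 0.37). UDP-glucuronosyltransferases (0.59, 21 rose and 1 fell, 2.60e-04), furrow and larval collagens (0.73, 10 of 23 rose, 2.94e-04), pharynx (0.88, 8 of 15, 9 over the list alone, 0.00156) and intestine genes (0.58, 7 of 18, 8 over the list alone, 0.00191) followed. Higher as well were col collagens (0.20, 39 rose and 13 fell; 41 and 16 over the list alone; 0.00321), cytochrome P450 genes (0.50, 15 rose and 2 fell, 0.00501), mitochondrially encoded genes (1.26, 8 of 12 rose and 1 fell, 0.00629) and molting genes (0.64, 7 rose and 1 fell, 0.00654; 0.0950 without N2 empty vector replicate 2). Cytosolic ribosomal protein genes (-0.26, 6 fell, 0 over the list alone, 0.0116) had 0.0608 without N2 empty vector replicate 2 and 0.166 and 0.0535 without met-2 replicate 1 or 2. Mitochondrial ribosomal protein genes (-0.26, 2 rose and 5 fell, 0 over the list alone, 0.0487) had 0.0925 without N2 replicate 3 and 0.157 and 0.147 without met-2 replicate 1 or 2. Removing the 3′ UTR trend gave a median of 0.13 and 0.901 for the cytosolic list, and -0.02 and 0.613 for the mitochondrial one. The lists in this paragraph that passed had adjusted p of 0.377 to 0.697 with an estimated correlation. Mitochondrial chaperones and proteases did not shift (median -0.02, adjusted p 0.870).

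The 2 mutants shared 126 higher and 28 lower genes against N2, with 10 in opposite directions, where 24.6 and 8.10 would be expected for unrelated lists. Both comparisons use the same N2 libraries. In 20 simulated data sets with no effect, this sharing gave a mean of 0.05 shared genes (highest 1) and a correlation of log2 fold changes of 0.51, against 0.32 in the data (0.49 with 16 libraries). The covariance was 0.0880 simulated and 0.209 in the data. Part of the excess may come from these shared controls. With no effect almost no gene passes the threshold, so the simulated count of shared genes cannot say how large that part is. The number expected for unrelated lists leaves the shared controls out. With 16 libraries 393 genes were shared in direction and 25 were opposite.

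By position in the WBcel235 annotation (Ensembl 115), genes higher in the mutants lay more often on chromosome arms, the regions outside the middle 1 of 3 equal parts of each autosome. In lin-65, 117 of 150 higher autosomal genes were on arms (78.0%, other genes 57.5%; Fisher exact odds ratio 2.62, 95% interval 1.76 to 3.99, two-sided adjusted p 6.16e-07). In met-2 it was 1154 of 1765 (65.4% against 56.5%, odds ratio 1.45, adjusted p 9.42e-12). The genes lower in lin-65 also lay there (33 of 43, 76.7%, adjusted p 0.0317). That call ended with 16 libraries (59.9%, unadjusted p 0.665) and with the 3′ UTR trend removed (57.1%, unadjusted p 1). The genes lower in met-2 lay there less often (50.6% against 59.2%, odds ratio 0.705, adjusted p 1.45e-12). Merging called genes within 100 kb of each other left 193 neighbourhoods of these, 81.3% on arms. Random lists matched on expression had 80% (95% range 75.4 to 84.5). For the genes higher in met-2 the share was 67.5% of 212 against 75.5% (71.4 to 79.7). For those higher in lin-65 it was 75.2% of 109 against 60.3% (53.3 to 67.2). The called genes of met-2 lie so densely that most merge, and more genes in a region merge further. Its neighbourhood shares therefore cannot tell whether genes are in excess on arms or lacking there. Genes are not independent replicates in these tests. No cco-1 RNAi response had an adjusted p under 0.05 here (range 0.172 to 0.860).

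Fold changes followed 3′ UTR length in most comparisons. Across 8761 genes with a mean log2 CPM above 3, which are not independent replicates, the Spearman correlation with annotated 3′ UTR length was 0.48 for the N2 response, 0.47 for lin-65 and -0.40 for met-2. It was -0.53 for met-2 minus N2, -0.55 for met-2 minus lin-65 and 0.38 for met-2 against N2. For lin-65 minus N2 (-0.11) and lin-65 against N2 (-0.09) it was weak. Cytosolic ribosomal protein genes have short 3′ UTRs (median 57 nt), as do col collagens (62.5 nt), while neuron (334 nt), molting (314 nt) and endoplasmic reticulum unfolded protein response genes (275 nt) have long ones. With this trend removed per library, the N2 response had cytosolic ribosome at a median of -0.16 (adjusted p 0.0776), mitochondrial ribosome at -0.14 (0.0951), glutathione S-transferases at -0.25 (0.0555), the respiratory chain at -0.14 (0.0951) and endoplasmic reticulum unfolded protein response genes at 0.15 (0.309). Vitellogenins (0.0218; 0.108 in 16 libraries, median -1.28 in both) and cytochrome P450 genes (8.39e-04; 0.00407) still passed in the 18 libraries. With an estimated correlation in 16 libraries, cytochrome P450 genes had 0.886. Major sperm proteins have no annotated 3′ UTR. In 2 libraries, lin-65 empty vector replicate 1 and met-2 cco-1 RNAi replicate 1, genes with long 3′ UTRs were low against their mates. The median deviation went from 0.67 in the shortest sixth of genes to -0.84 in the longest in the first, and from 0.85 to -1.73 in the second.

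**Figure D5:**
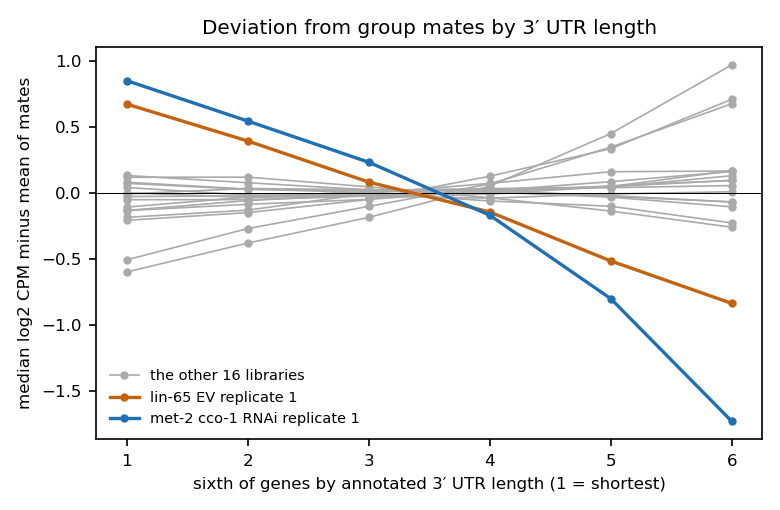
Median log2 CPM minus the mean of the group mates (vertical) against sixths of genes by annotated 3′ UTR length, shortest to longest (horizontal), 1 line per library. Lin-65 empty vector replicate 1 (0.67 to -0.84) and met-2 cco-1 RNAi replicate 1 (0.85 to -1.73) are coloured, the other 16 libraries grey.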

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

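The tests of 3′ UTR length below were chosen after the result was seen, as were the alternatives with 16 libraries, with library weights and with the trend removed.

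These lists stood out because the response to cco-1 RNAi differed between strains in a test of the difference itself (camera, adjusted over 38 lists). For lin-65 minus N2 the lower lists were col collagens (median -0.62, adjusted p 5.17e-16), vitellogenins (-1.50, 4.90e-04), UDP-glucuronosyltransferases (-0.24, 0.00914), cytochrome P450 genes (-0.28, 0.00937), intestine (-0.35, 0.0121), endoplasmic reticulum unfolded protein response (-0.38, 0.0278) and C-type lectins (-0.25, 0.0477). The higher lists were the respiratory chain (0.29, 4.96e-04), mitochondrial ribosome (0.19, 0.00937), major sperm proteins (0.26, 0.0121), tricarboxylic acid cycle (0.24, 0.0225), glycolysis (0.18, 0.0238), other sperm genes (0.16, 0.0238), germ granule genes (0.17, 0.0371) and cytosolic ribosome (0.06, 0.0477). With an estimated correlation none passed (0.555 to 0.710).

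For met-2 minus N2 the lower lists were vitellogenins (median -3.73, adjusted p 2.10e-07), endoplasmic reticulum unfolded protein response (-0.54, 0.00179), molting (-0.69, 0.00202), oocyte (-0.45, 0.0299) and adult cuticle collagens (-0.69, 0.0405). The higher lists were mitochondrial ribosome (0.61, 2.37e-05), glutathione S-transferases (0.69, 1.12e-04), cytosolic ribosome (0.49, 8.51e-04), respiratory chain (0.38, 0.00117) and mitochondrial import (0.64, 0.00842). For met-2 minus lin-65 they were oocyte (-0.76, 1.93e-04), vitellogenins (-2.34, 1.93e-04), molting (-0.72, 0.00157) and germ granule genes (-0.38, 0.00641) among the lower. Among the higher were col collagens (0.44, 1.93e-04), glutathione S-transferases (0.62, 4.45e-04), UDP-glucuronosyltransferases (0.38, 0.00157), mitochondrial ribosome (0.51, 0.00591), innate immune genes (0.51, 0.0198) and cytosolic ribosome (0.29, 0.0219). With an estimated correlation the adjusted p was 0.493 to 0.869 for met-2 minus N2 and 0.636 to 0.674 for met-2 minus lin-65.

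Leaving out any 1 library of the groups compared kept an adjusted p under 0.05 for 16 of these 35 list differences. For lin-65 minus N2 these were col collagens, vitellogenins and the respiratory chain. For met-2 minus N2 they were vitellogenins, unfolded protein response, mitochondrial and cytosolic ribosome, glutathione S-transferases, respiratory chain and import, and for met-2 minus lin-65 vitellogenins, oocyte, molting and germ granule genes, glutathione S-transferases and UDP-glucuronosyltransferases. In lin-65 minus N2, N2 empty vector replicate 2 bore on UDP-glucuronosyltransferases (0.104 without it), cytochrome P450 genes (0.104), intestine (0.0612), C-type lectins (0.221), major sperm proteins (0.221), other sperm genes (0.159), germ granule genes (0.317), glycolysis (0.0873), unfolded protein response (0.104) and cytosolic ribosome (0.324). Without lin-65 empty vector replicate 2 the mitochondrial ribosome had 0.183, cytosolic ribosome 0.789 and unfolded protein response 0.406, and without replicate 1 the tricarboxylic acid cycle had 0.215 and C-type lectins 0.300. Without lin-65 cco-1 RNAi replicate 1 UDP-glucuronosyltransferases had 0.0955 and cytochrome P450 genes 0.0570, and without empty vector replicate 3 intestine had 0.101. In met-2 minus N2, molting genes had 0.0800 without N2 empty vector replicate 2, adult cuticle collagens up to 0.197 and oocyte genes up to 0.192 (each without met-2 cco-1 RNAi replicate 3). In met-2 minus lin-65, leaving out met-2 cco-1 RNAi replicate 1 gave 0.0523 for col collagens, 0.357 for the mitochondrial ribosome, 0.269 for innate immune genes and 0.249 for the cytosolic ribosome, which had 0.501 without lin-65 empty vector replicate 1.

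With the 3′ UTR trend removed further lists missed the threshold, some of them among these 16, most with a smaller median (in brackets, the values when it was removed in 16 libraries). In met-2 minus N2 the cytosolic ribosome had a median of 0.08 and adjusted p 0.813 (0.24, 0.147), oocyte genes -0.25 and 0.215 (-0.04, 0.410) and the unfolded protein response -0.24 and 0.118 (-0.21, 0.0239). In met-2 minus lin-65 col collagens had 0.13 and 0.172 (0.11, 0.254), germ granule genes -0.21 and 0.172 (-0.12, 0.0739), cytosolic ribosome -0.14 and 0.172 (-0.06, 0.735) and glutathione S-transferases 0.20 and 0.211 (0.16, 0.140). The mitochondrial ribosome had 0.13 and 0.365 (-0.04, 0.735), innate immune genes 0.20 and 0.316 (0.07, 0.334), UDP-glucuronosyltransferases 0.29 and 0.0521 (0.34, 0.00319) and molting genes -0.64 and 0.0521 (-0.48, 0.0178). In lin-65 minus N2 germ granule genes had 0.0532 (0.0939), but with a median of 0.20 (0.21) that was no smaller than before, so this does not tie their shift to the trend. Major sperm proteins have no annotated 3′ UTR and were not tested.

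The planned edgeR fit called no gene in these differences (0, 0 and 0; at an unadjusted p under 0.05, 480, 2603 and 1723; DESeq2 5, 153 and 1). With the block it called 0, 32 and 0, and without a filter on low counts 0, 12 and 0. With 16 libraries it called 23, 127 and 1, with the 3′ UTR trend removed 3, 42 and 1, and with only the groups compared 0, 4 and 0. Leaving out met-2 cco-1 RNAi replicate 1 gave 11 for met-2 minus N2. All 25 of the 25 splits of the libraries gave as many genes in each of the 3 differences, which they must where the real count is 0, so the splits say nothing about chance here. The highest of the other splits gave 40, 8 and 0 genes, and what sets apart the split that gave 40 was not tested. At an unadjusted p under 0.05 the other splits gave up to 3834, 3214 and 3175 genes, more than the real groups. These splits can carry the cco-1 RNAi response itself into the difference, so their counts are no reference for equal responses.

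In these data 2 libraries lie apart from their mates. The root mean square deviation was 1.02 for lin-65 empty vector replicate 1 and 1.16 for met-2 cco-1 RNAi replicate 1, and 0.856 at most for the other 16. Depth does not account for it, since with all libraries thinned to the smallest total the lower of the 2 was still 1.18 times the highest other. Nor is lin-65 empty vector replicate 1 an N2 library: on 200 genes chosen without it, it lay at 0.901 between N2 (0) and lin-65 (1), with the N2 libraries at -0.01 to 0.01. It fell short of its mates (0.986 and 1.01), which the test had asked it to reach. The N2 libraries and the mates set 0 and 1 on this scale, so a library left out can fall short for that reason alone. An admixture was not tested. On such genes met-2 cco-1 RNAi replicate 1 lay at 0.916 between N2 and met-2, with its mates at 0.949 and 1.05, so it is not an N2 library either. A loss of counts from genes with long 3′ UTRs may be part of the difference (Spearman correlation of -0.543 and -0.713, lowest of the others -0.303). With the trend removed the 2 deviations fell to 0.850 and 0.795, and the ratio was still 1.22. The removal rests on a trend fitted to annotated lengths and may be incomplete, so this cannot say whether the loss is the whole difference.

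What causes the loss stays open: RNA quality, library preparation and a difference between cultures were not tested, and no biological explanation was tested. The 2 libraries are of different strain and diet but share replicate number 1, and their deviations correlate at 0.69 across genes, which are not independent replicates. Replicates 2 and 3 of the same 2 groups correlate at 0.53 and 0.31, partly because deviations in a group of 3 add up to 0. With replicate 1 of the other 4 groups the 2 libraries correlate at -0.28 to 0.34, so a factor shared by that number stays open. List differences between strains that follow 3′ UTR length could in part reflect them. With 16 libraries the mitochondrial ribosome (0.527) and cytosolic ribosome (0.320) in met-2 minus lin-65 turned to the opposite direction.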

How the results depend on the processing

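The settings with 16 libraries, with library weights, with a block in the N2 libraries alone and with the 3′ UTR trend removed were chosen after the results were seen. Counts below are genes past the threshold, in the order N2, lin-65 and met-2 on cco-1 RNAi, then the differences lin-65 minus N2, met-2 minus N2 and met-2 minus lin-65, then lin-65 and met-2 against N2, unless named. For comparison the reported counts are 127, 108, 167, 0, 0, 0, 214 and 4616. Unless stated, the cause was not tested.

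No named gene reversed its direction while called under any setting run. Of the results of named genes, each counted per comparison, 309 kept their side of the threshold under DESeq2, 304 under DESeq2 size factors, 307 with the replicate block, 304 with 16 libraries, 305 with library weights and 275 with the trend removed. Using only the groups compared, 248 kept it and 55 lost it, with fewer libraries behind each spread. Over the runs leaving out 1 library, 1646 values kept their side and 309 lost it. For gene lists, 303 of 304 results held under DESeq2 size factors, 293 with the block, 287 without a filter and 290 with the stricter filter. Of these 304 (38 lists in 8 comparisons), 101 lost a call with an estimated correlation and 203 held, and fry lost 70. Leaving out 1 library, 2259 list results held, 132 lost and 114 gained a call, and 3 reversed.

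DESeq2 gave 547, 280, 357, 5, 153, 1 and 375 genes in the first 7 comparisons. With DESeq2 size factors or the filter of 50 counts each count stayed within 1.5 times the reported one. Without a filter met-2 minus N2 gave 12. The replicate block gave 200 in N2 and 32 in met-2 minus N2. At the threshold of 0.01 the counts were 50 in N2, 42 in lin-65, 92 in met-2, 102 for lin-65 and 1939 for met-2 against N2, fewer by construction. Using only the groups compared gave 2860 in N2, 19 in lin-65, 34 in met-2, 4 in met-2 minus N2 and 51 in lin-65 against N2. In N2 the spread is then not shared with the 2 libraries that lie apart.

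With 16 libraries the counts were 2828, 173, 300, 23, 127, 1, 523 and 7517, the 2 libraries no longer adding to the spread. In met-2 on cco-1 RNAi the mitochondrial ribosome (adjusted p 0.939), innate immune genes (0.939) and glutathione S-transferases (0.939) reversed. In met-2 minus lin-65 the mitochondrial ribosome (0.527) and cytosolic ribosome (0.320) reversed. Shared genes rose to 112 for N2 and lin-65, 143 for N2 and met-2, and 393 for the mutants against N2. Of genes lower in lin-65, 59.9% lay on arms, no longer past the threshold.

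Limma voom with library weights gave 4164, 1576, 1124, 50, 2382, 126, 1048 and 8088 genes. The replicate block in the 6 N2 libraries alone gave 4351 in N2.

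With the trend on 3′ UTR and coding length removed, N2 had 299 genes, met-2 267, the differences 3, 42 and 1, and lin-65 against N2 324. The cytosolic ribosome reversed in lin-65 (0.659) and in met-2 minus lin-65 (0.172), and 57.1% of genes lower in lin-65 lay on arms. Removed in 16 libraries, the counts were 2074, 206, 363, 33, 134, 1 and 515 in the first 7 comparisons. The cytosolic ribosome then reversed in lin-65 (0.481), in met-2 minus lin-65 (0.735) and in met-2 against N2 (0.794), and the mitochondrial ribosome in met-2 minus lin-65 (0.735). Removed with the replicate block, N2 had 666 genes. Apart from the trend, the reported fit was used to compare response size over genes called in lin-65. The response in met-2 minus that in N2 was 0.00 as a median of fitted fold changes and 0.50 as a mean.

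Leaving out 1 library of the groups compared at a time, counts ranged from 50 to 74 in N2, 33 to 133 in lin-65, 91 to 180 in met-2, 0 to 0 in lin-65 minus N2, 0 to 11 in met-2 minus N2, 0 to 1 in met-2 minus lin-65, 99 to 201 in lin-65 against N2 and 2411 to 3681 in met-2 against N2, all with fewer libraries. Leaving out a library outside the comparison, which only shares the spread, gave up to 863 in N2, 226 in lin-65, 230 in met-2, 1, 21 and 0 in the differences, 342 in lin-65 against N2 and 6095 in met-2 against N2. The values above 0 came without met-2 cco-1 RNAi replicate 1, or without lin-65 empty vector replicate 1 for met-2 and met-2 minus N2. In met-2 on cco-1 RNAi the adjusted p ranged from 2.95e-06 to 0.918 for the mitochondrial ribosome, 0.00512 to 0.854 for innate immune genes and 6.12e-10 to 0.759 for major sperm proteins. Depth limits what can be called, as a count of 3 is 0.153 to 0.510 CPM.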

Other observations

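The tests of a response of ribosomal genes, of linked variants, of loss of met-2 function and of neighbourhoods on chromosome arms below were chosen after the result was seen.

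The fall of cytosolic ribosomal protein genes on cco-1 RNAi in N2 was set against the trend on 3′ UTR length. For the 75 genes with an annotated 3′ UTR the median log2 fold change was -0.48 (SD 0.40), and lists matched on 3′ UTR length and expression had a median of -0.30 (-0.41 to -0.17). The list lay at percentile 0.35 of these, but they were not matched on coding length (Spearman correlation of 0.27 with the N2 response). For met-2 against N2 on empty vector the same list lay at percentile 0.11, with a median of -0.245. There, removing the trend on 3′ UTR and coding length turned the median to 0.141. The percentile therefore cannot tell whether the trend accounts for the whole fall. With the trend removed the median was -0.16 (SD 0.37) and camera's adjusted p 0.0776, the call ending because most of the fold change went with the trend. Whether the part beyond the matched lists is a response of these genes to cco-1 RNAi stays open, since the trend differs between the 2 N2 groups and its removal would take a real change of short genes with it.

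In the 6 met-2 libraries 6 genes were nearly absent. The rule asked for a mean of at least 3 CPM in each of the other strains. Every single met-2 library also had to lie more than 8-fold below the lower of those means. All but plk-3 were chosen after their values were seen. Means over 6 libraries in N2, lin-65 and met-2 were 133, 74.2 and 0.564 CPM for plk-3, 37, 25.9 and 0.642 for F55G1.6, 53.6, 64.3 and 3.58 for C01A2.4, 5.98 (SD 6.49), 4.98 (SD 4.11) and 0.207 for D1014.7, 7.34 (SD 8.05), 5.90 (SD 6.08) and 0.0531 for D1014.6, and 5.03, 3.76 and 0.226 for T01G5.7. Linked strain variants such as deletions may account for part of them, since 2 adjacent pairs lay among the 6 (plk-3 with F55G1.6 on chromosome IV, D1014.7 with D1014.6 on V, WBcel235), and 0 of 10000 random sets had as many (highest 1). The second pair was uneven among the N2 and lin-65 libraries, so its absence in met-2 is less sure. Adjacent here means next to each other among tested genes, and the random sets leave out that neighbours can change together. Adjacency therefore does not single out deletions, and loss of met-2 function cannot be told apart from them. The median log2 fold change of the 6 genes in lin-65 against N2 was -0.448, but an effect of met-2 need not be shared by lin-65, and genomic reads are not used here.

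In the lin-65 libraries 2 genes were nearly absent, also chosen after their values were seen: F59C6.18 (29.4 CPM in N2, 0.663 in lin-65, 231 in met-2) and Y49G5A.1 (7.89, 0.166 and 38.7 CPM).

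The excess on chromosome arms of genes higher in lin-65 and in met-2 exceeded 10000 lists matched on mean expression, with a one-sided permutation p of 1e-04 and 1e-04, the smallest they can give. With called genes within 100 kb merged, 75.2% of 109 neighbourhoods lay on arms for genes higher in lin-65, against 60.3% (95% range 53.3 to 67.2) in random lists matched on expression and merged alike. For genes higher in met-2 it was 67.5% of 212, below the random 75.5% (71.4 to 79.7). There 1765 genes merged into these 212, and more genes on arms merge further, so this share cannot test the excess. The cause of the excess was not tested.

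For the 5 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real counts were 127 (N2), 108 (lin-65) and 167 (met-2) on cco-1 RNAi, and 214 (lin-65) and 4616 (met-2) against N2, each 1 of 10, and the highest other split gave 0 in each.

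The differences lin-65 minus N2 and met-2 minus N2 share the N2 libraries. Their log2 fold changes correlated at 0.49 across genes, against 0.50 in simulated data with no effect, and their covariance was 0.262 against 0.176. With 16 libraries the correlation was 0.62 and the covariance 0.351. There 18 genes were lower in both where 0.167 would be expected for unrelated lists, and 0 were shared in the simulations of 18 libraries. With no effect almost no gene passes, and the expected number leaves the shared libraries out. Neither value says how many of the 18 come from the shared N2 libraries.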
